A study of Homo sapiens with 6 samples.

How the data were processed

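The series holds RNA sequencing of 6 human libraries labelled MB231 breast cancer cells, 3 labelled shNC (wild type) and 3 labelled shPAK5 (PAK5 knockdown), which were grouped and numbered from their titles. Per the labels, the libraries were made with the NEBNext Ultra RNA kit. The aligner, the counting tool and whether strand was used are not given in the sources used here. The deposited table, made by the authors, gives FPKM per gene for all 6 libraries, per the file headers, with gene coordinates, lengths and biotypes. The submitters' processing notes name the mouse build mm10, but the table holds human genes. All 58735 gene IDs, coordinates and exonic lengths matched the human annotation GENCODE 29 (GRCh38), 58723 symbols matched, and no mouse gene ID was present, so coordinates are given in GRCh38.

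FPKM is not a count. The product of FPKM and gene length came out as whole multiples of 1 step per library, within 0.001, for 100% of the values, which gave the reads behind each value. They summed to between 15085168 and 18146091 reads per library. The totals by which the authors' FPKM values were divided were proportional to median-of-ratios size factors, so that the values were already scaled in this way when deposited. Mitochondrial genes took 11.8 to 12.8% of the reads. No pair of libraries of a group agreed within sampling noise. Chi-square per degree of freedom was 2.32 to 9.31 within groups over 13710 genes with at least 60 reads, and each library was counted as 1 replicate. A value of 0 was given an upper limit of 3 reads, and such limits cover counting error only.

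The main test was limma 3.58.1 in R 4.3.3 (lmFit and eBayes with trend) on log2(FPKM + 1), with the group as the only term, over the 11237 genes with a mean of at least 1 FPKM over the 6 libraries, and Benjamini-Hochberg adjustment at 0.05. Fold changes are on the log2(FPKM + 1) scale and understate the change of low genes, so the ratio of mean FPKM is printed for ALDH1A1, SNCG, TGFA and MT-TQ. Gene lists were tested with limma's camera at its preset inter-gene correlation of 0.01, adjusted over the 34 lists with at least 5 tested members out of 37 written before the data were examined. camera with an estimated correlation and fry were run beside it. The result of 1 of the tested lists is not reported here. An exact permutation test of 3 against 3 libraries cannot go below p = 0.1. The one planned for PAK5 could not be made, since all 6 values were 0. Levels of lists were compared with 10000 random lists of protein-coding genes of the same size. A list of gastrointestinal epithelium (27 genes) and a list of 3 genes with a known state in the labelled line were written after the levels had been seen, and the first was tested between groups with camera, also after its levels had been seen.

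Named genes were fixed by a rule before the data were examined: PAK5, then up to 12 rises and 12 falls with the largest change among protein-coding genes past the threshold, with at least 5 FPKM in the higher group and no overlap between groups, then up to 4 passing members of each list. A list without a passing member is illustrated by its most abundant genes. The rule gave 8 rises and 3 falls, and genes named outside it are stated as such. The main tests, the 37 gene lists and the alternatives were fixed before the data were examined. The GC correction, alone, with limma-voom and with single libraries left out, was chosen after seeing the data, as were the added lists with their tests and the tests of PAK5, of lineage genes and of the GC trend. The alternatives were 2 pseudocounts (0.1 and 0.01), 2 filters (none and a mean of at least 5 FPKM), 3 scalings, 2 variance models, array weights, limma-voom on the recovered reads, a replicate block, protein-coding genes only, a test against a fold of 1.5, and each library left out in turn. The GC correction subtracted from each library a loess curve (span 0.3) of its deviations on the GC content of the transcripts.

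The scripts were tested on simulated data with changed genes, the depth of these libraries and a common dispersion of 0.00225 for all genes. Genes were drawn independently, so differences in spread between genes and correlations between genes were left out. Recovery and false calls in the real libraries can therefore differ from those given here. In this simulated comparison of 3 against 3 over 11256 genes, limma recovered 38% of the genes changed 1.25-fold, 91.7% of those changed 1.5-fold and 91.5% of those changed 2-fold, with 12 false calls, and limma-voom recovered 74%, 100% and 95.7% with 7 false calls. With the libraries' GC trends added, over 11254 genes, false calls came to 11 in limma and 32 in limma-voom, and to 14 and 12 after the GC correction. Figures were drawn with matplotlib in Python.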

Results

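Gene expression was measured by RNA sequencing in 6 human libraries of cells labelled MB231, taken here as MDA-MB-231, a breast cancer line known for a mesenchymal state and for lacking estrogen receptor. The libraries fell into 2 groups of 3. The shNC libraries were labelled wild type, and the shPAK5 libraries were labelled as a knockdown of PAK5, a p21-activated serine/threonine kinase. The values were FPKM (fragments per kilobase of exon, scaled to the depth of the library) for 58735 genes, and the reads recovered from them came to 17464058, 16522885 and 16621082 in shNC replicates 1 to 3 and to 18146091, 16862133 and 15085168 in shPAK5 replicates 1 to 3, with 50608025 over the shNC group and 50093392 over the shPAK5 group. Nothing in the labels said whether the replicates came from separate cultures, so p-values measure only the spread between these libraries, which can be technical.

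PAK5 was examined first, because its level would check the labels. PAK5 (ENSG00000101349) lies on the minus strand of chromosome 20 from 9537389 to 9839041 in GRCh38, with 4929 bp of exons in 12 blocks. It was at 0 FPKM, and at 0 reads, in each of the 3 shNC and each of the 3 shPAK5 libraries. A count of 0 allows up to 3 reads, which corresponded to 0.0335 to 0.0403 FPKM in a single library, to 0.0119 FPKM over the pooled shNC libraries and to 0.0121 FPKM over the pooled shPAK5 libraries, for counting error only. PAK5 mRNA was therefore not detectable at this depth in either group, no fold change could be given, and the knockdown could not be checked from these values. Its closest relatives were PAK4 at 13.4 ± 0.960 FPKM (SD, n = 3) in shNC and 12.8 ± 0.374 in shPAK5, and PAK6 at 0.688 ± 0.105 and 0.717 ± 0.118. PAK1 was at 13.5 ± 0.283 and 13.6 ± 0.509 FPKM, PAK2 at 18.7 ± 1.25 and 20.9 ± 1.28, and PAK3 had 0 reads in all 6 libraries. These relatives and the cell-state genes given as levels lie outside the rule for named genes and were chosen after their values were seen.

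Libraries labelled shPAK5 were compared with libraries labelled shNC, by the labels a knockdown of PAK5 and its control, although no PAK5 mRNA was detected in either. The differences were few and small. ALDH1A1, a dehydrogenase that makes retinoic acid, rose from 27.2 ± 0.510 to 47.1 ± 1.77 FPKM (SD, n = 3), a ratio of 1.73, and SNCG, which encodes gamma-synuclein, fell from 25.4 ± 1.52 to 13.8 ± 0.596 FPKM, a ratio of 0.545. TGFA, a ligand of the EGF receptor, rose from 3.39 ± 0.278 to 5.95 ± 0.333 FPKM, a ratio of 1.75, and EDN1, the precursor of a vasoconstrictor peptide, rose from 8.43 ± 0.353 to 12.5 ± 0.423 FPKM. BHLHA15, a transcription factor of secretory cells, fell from 7.18 ± 0.306 to 4.09 ± 0.553 FPKM, and OASL, an interferon-induced protein, fell from 15.5 ± 0.454 to 11.8 ± 0.379 FPKM. For each of these genes all 3 shPAK5 libraries lay on the same side of all 3 shNC libraries, which the rule for named genes required.

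The other rises of protein-coding genes were smaller on the log2 scale. TMED4, a cargo receptor of the early secretory pathway, rose from 32.0 ± 0.365 to 44.6 ± 1.54 FPKM. SGPP1, a phosphatase of sphingosine phosphate, rose from 7.18 ± 0.264 to 10.2 ± 0.238 FPKM, and SLC40A1, the iron exporter ferroportin, rose from 7.06 ± 0.197 to 9.90 ± 0.0766 FPKM. TNFSF15, a cytokine of the TNF family, rose from 6.08 ± 0.131 to 8.41 ± 0.298 FPKM. VIL1, the actin-bundling protein villin of microvilli, rose from 6.37 ± 0.170 to 8.93 ± 0.168 FPKM. The exons of VIL1 overlap those of USP37 on the other strand over 3045 of 6920 bp, so that without strand information part of its reads cannot be assigned with certainty. USP37 differed by -0.04 ± 0.08 (SE) on the log2 scale (limma adjusted p = 0.828).

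These genes came from limma on log2(FPKM + 1) over 11237 genes, of which 13 passed a Benjamini-Hochberg adjusted p of 0.05, 10 higher and 3 lower in shPAK5. On that scale the change was 0.77 ± 0.04 (SE) for ALDH1A1 (adjusted p = 0.00142) and -0.83 ± 0.06 for SNCG (adjusted p = 0.0030). ALDH1A1 lies on chromosome 9 from 72900662 to 73080442 and SNCG on chromosome 10 from 86958618 to 86963260 (GRCh38). For the other 9 genes the size of the change ranged from the fall of OASL, -0.37 ± 0.05 (limma adjusted p = 0.0498), to the fall of BHLHA15, -0.69 ± 0.08 (limma adjusted p = 0.0421). The remaining 2 of the 13, LBH and the mitochondrial tRNA gene MT-TQ, did not meet the rule for named genes and were chosen for mention after their values were seen. MT-TQ rested on 5 to 13 reads per library and did not pass in limma-voom (adjusted p = 0.198), whereas LBH rose from 2.21 ± 0.0373 to 3.52 ± 0.175 FPKM. No gene passed with at least a 2-fold change in limma on the log2(FPKM + 1) scale, or in limma-voom. MT-TQ, from 4.63 ± 0.445 to 9.69 ± 0.852 FPKM, had a ratio of mean FPKM of 2.09 but a fold of 1.90 on that scale. An unadjusted p under 0.05 together with a 2-fold change was found for 10 genes in limma and for 21 in limma-voom. Without regard to adjustment, 1908 genes had a p under 0.05 against 562 expected by chance for independent libraries, while the splits that put shNC replicate 1 with 2 shPAK5 libraries gave 1225, 865 and 713. The groups did not overlap in 23.1% of the tested genes, against 10% by chance. The 95% interval of the change lay within 1.5-fold for 95.16% of the tested genes and within 2-fold for 98.66%. These intervals are also on the log2(FPKM + 1) scale, which understates the change of low genes.

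**Figure D1:**
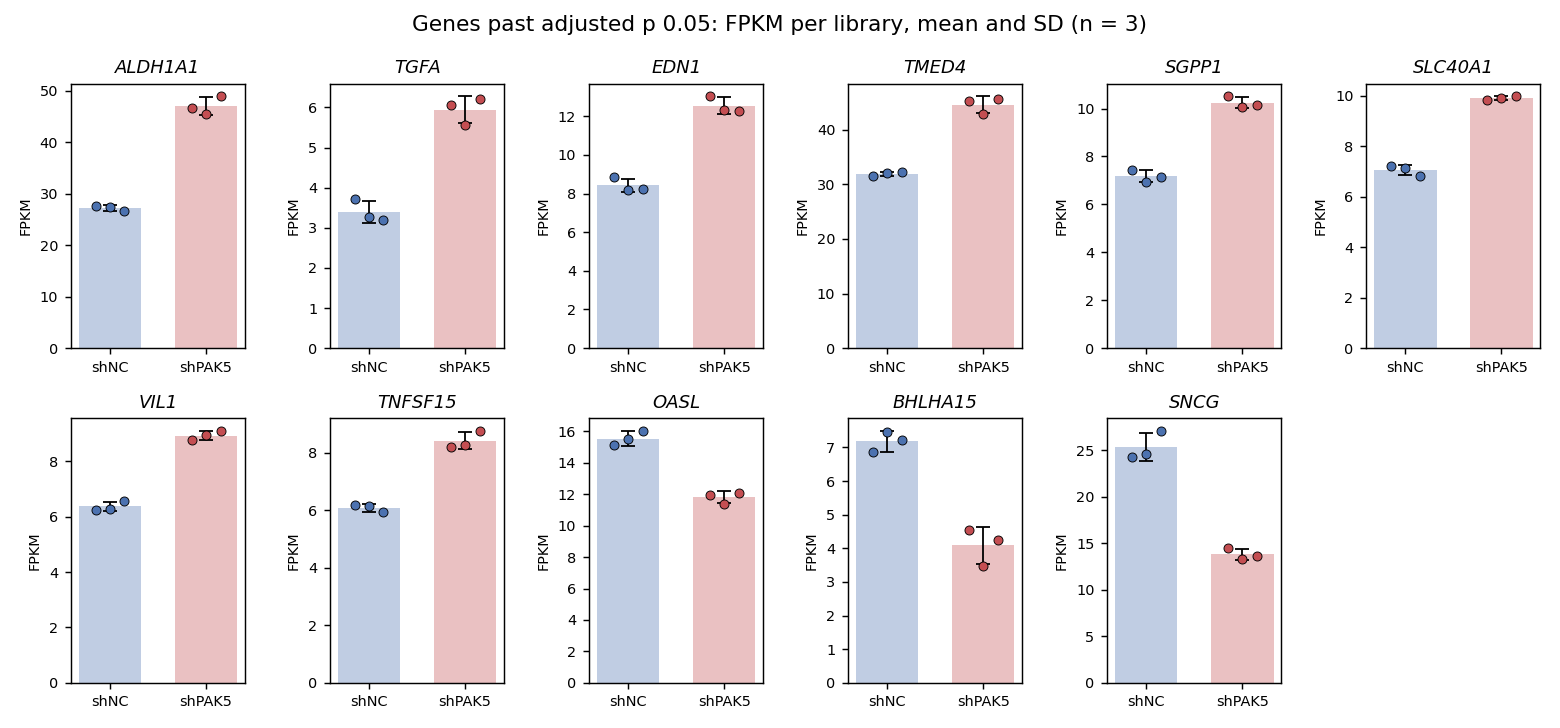
FPKM of the 11 protein-coding genes chosen by the fixed rule, one panel per gene, with the vertical axis starting at 0. Points are single libraries, bars are group means and error bars are SD (n = 3). In each panel the groups do not overlap, which the rule required, as for ALDH1A1 with means of 27.2 and 47.1 FPKM.

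The count of 13 changed when single libraries were left out. It was 915 without shNC replicate 1, and between 2 and 5 without any of the other 5 libraries, with ALDH1A1 and SNCG past the threshold in each of these fits. limma-voom on the recovered reads called 117 genes, 95 higher and 22 lower, 12 of them shared with the 13, and quantile normalization moved the split to 13 higher and 7 lower.

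In camera at its preset correlation, 2 lists passed, G2/M genes downward and hypoxia genes upward in shPAK5. Neither passed with an estimated correlation (adjusted p = 0.747 and 0.412). As many lists passed in 3 of the 10 splits of the libraries into 3 against 3, the real split included. Of the 35 tested G2/M genes, 30 had a negative change, with a median of -0.08 on the log2 scale (camera adjusted p = 0.000481 over 34 lists, and adjusted p = 0.747 with an estimated correlation). None passed over all genes in limma, MYBL2 fell over all genes in limma-voom (adjusted p = 0.0362), and 5 fell in limma when adjusted over the list alone. They were MYBL2, a transcription factor of the cycle, from 96.7 ± 6.16 to 81.4 ± 1.97 FPKM (SD, n = 3), the mitotic kinases AURKB, from 21.8 ± 0.441 to 18.7 ± 0.334, and PLK1, from 23.4 ± 1.76 to 19.8 ± 0.314, together with UBE2C and KIF2C. The call was also lost without shNC replicate 1 (camera adjusted p = 0.184). With the GC correction, chosen after seeing the data, the list passed without that library (camera adjusted p = 1.54e-05). Without the GC correction and with all libraries, the adjusted p was 0.211 in fry and 0.0860 in camera with arrayWeights. Over 27 alternatives the adjusted p ranged from 2.04e-10 to 0.747.

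Of the 16 tested hypoxia genes, 14 had a positive change, with a median of 0.13 on the log2 scale (camera adjusted p = 0.000835, and adjusted p = 0.412 with an estimated correlation). None passed over all genes in limma, BNIP3L and CA9 rose over all genes in limma-voom (adjusted p = 0.0164 and 0.0490), and 4 rose in limma when adjusted over the list alone. The carbonic anhydrase gene CA9 went from 123 ± 4.26 to 143 ± 2.99 FPKM (SD, n = 3), and BNIP3L, a receptor for the removal of mitochondria, from 20.2 ± 1.77 to 26.1 ± 1.12. P4HA1, a collagen prolyl hydroxylase, went from 19.3 ± 2.20 to 23.1 ± 0.919 and the peptide hormone gene ADM from 2.84 ± 0.154 to 3.69 ± 0.478. The adjusted p ranged from 1.33e-05 to 0.412 over 27 alternatives, of which 26 kept the call. The call was lost only with the estimated correlation, which was -0.0259 for this list. That value lies below the preset 0.01, so correlation between these genes does not account for the loss. A list of gastrointestinal epithelium, written after its levels had been seen, was higher in shPAK5 (camera unadjusted p = 4.89e-06, and p = 0.00816 with an estimated correlation), with 13 of its 15 tested members positive. That list holds VIL1, a gene named above for its rise, so its test is not independent evidence of the direction. Members of lists that are named for passing over a list alone, here and in what follows, were chosen after their values were seen.

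**Figure D2:**
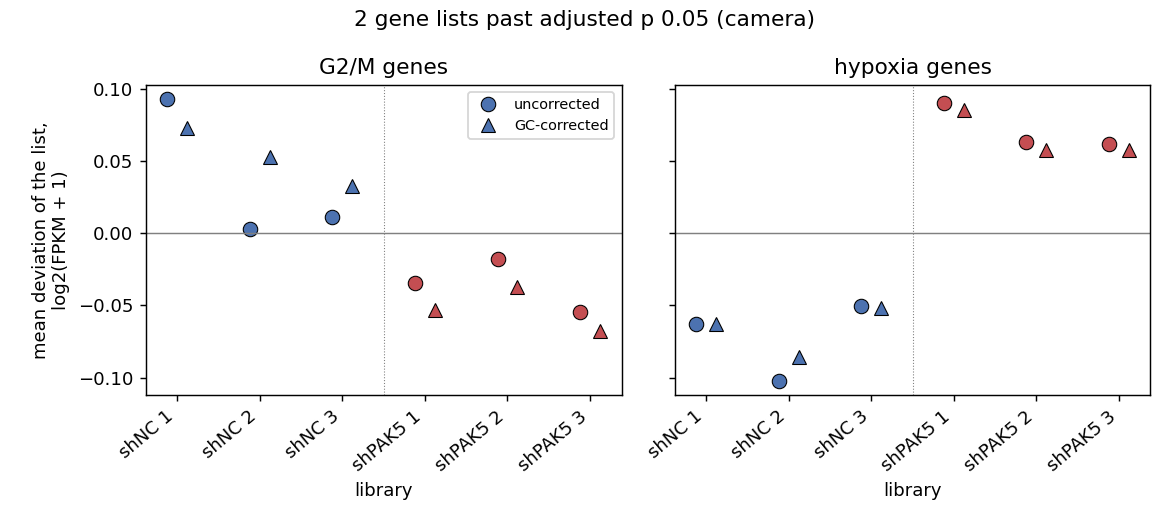
Mean deviation of the G2/M and hypoxia lists from each gene's mean over the 6 libraries, on the log2(FPKM + 1) scale, for each library before (circles) and after (triangles) a correction for GC content. Blue symbols are shNC and red symbols shPAK5. All 3 shPAK5 libraries lie below all 3 shNC libraries for the G2/M list and above them for the hypoxia list, and the G2/M list of shNC replicate 1 lies highest.

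The other 32 lists did not pass (camera adjusted p from 0.104 to 0.999). What is said of their members refers to limma unless limma-voom is named. Over all lists limma-voom, without the GC correction, called 17 members over all genes, 14 of them not past in limma. Of these 14, only SLC7A5, CA9 and BNIP3L passed in limma with the GC correction. Among the remaining lists of the cell cycle, the 34 tested G1/S genes had 22 negative changes and none passed alone (camera adjusted p = 0.137), with PCNA at 206 ± 3.93 and 211 ± 1.95 FPKM in shNC and shPAK5 (SD, n = 3). Of the 15 tested replication-dependent histone genes, 12 had a positive change (camera adjusted p = 0.104, and adjusted p = 0.747 with an estimated correlation). The list was written for histone mRNAs without a poly(A) tail, and whether the transcripts measured here lack one cannot be told from these values. The list passed at a mean of at least 5 FPKM (camera adjusted p = 0.0113) and without shPAK5 replicate 3 (camera adjusted p = 0.0217), and over the alternatives the adjusted p ranged from 0.00490 to 0.747. Among these genes HIST1H1C rose from 62.3 ± 5.43 to 85.8 ± 2.30 FPKM and HIST1H4I from 24.8 ± 0.461 to 28.4 ± 1.13 when adjusted over the list alone, and over all genes neither passed in limma, while HIST1H1C did in limma-voom (adjusted p = 0.00796). Of the 21 CDK inhibitor and p53 target genes none passed in limma and MDM2 rose in limma-voom (adjusted p = 0.0343), with TNFRSF10B at 37.2 ± 1.36 and 35.3 ± 0.756 FPKM. None of the 26 genes of DNA double-strand break repair, the 21 pro-apoptotic genes or the 11 anti-apoptotic genes passed, and XRCC6 was at 126 ± 2.20 and 124 ± 2.73, CYCS at 39.0 ± 6.67 and 43.7 ± 0.412 and BCL2L1 at 55.8 ± 1.45 and 59.0 ± 1.85 FPKM.

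Lists of adhesion, invasion and cell state did not pass as groups. None of the 19 integrin and focal adhesion genes passed, and ITGB4 was at 395 ± 32.5 and 415 ± 6.90 FPKM in shNC and shPAK5 (SD, n = 3). When adjusted over the list alone, 2 of the 14 tested matrix metalloproteinase and protease genes rose, MMP7 from 14.5 ± 0.626 to 18.6 ± 1.55 and SERPINE2 from 63.1 ± 2.90 to 70.7 ± 0.466 FPKM, and 1 fell, PLAT from 8.13 ± 0.233 to 6.81 ± 0.220. MMP7 also rose over all genes in limma-voom (adjusted p = 0.0423). Of the 15 tested epithelial genes, CDH1 rose from 4.64 ± 0.180 to 5.84 ± 0.0905 and EPCAM from 109 ± 7.69 to 128 ± 2.72 FPKM, while KRT18 and ESRP2 fell, in each case over the list alone, and CDH1 and EPCAM also rose over all genes in limma-voom (adjusted p = 0.0377 and 0.0474). Of the 10 tested mesenchymal genes, VIM, CD44, TGFBI and AXL rose, and COL6A1 and ITGA5 fell, over the list alone, with VIM at 149 ± 10.2 and 164 ± 3.09 FPKM, and COL6A1 fell over all genes in limma-voom (adjusted p = 0.0256). Of the 16 tested TGF-beta target genes, 3 rose and 2 fell over the list alone, among them ID3 from 3.12 ± 0.359 to 1.66 ± 0.119 FPKM, which also fell over all genes in limma-voom (adjusted p = 0.0279). None of the 19 YAP and TAZ target genes passed, and MYOF was at 93.4 ± 3.36 and 90.2 ± 2.06 FPKM.

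Of the 14 tested stemness genes, ALDH1A1 rose over all genes, and CD44, ALDH1A3 and SOX4 rose in addition over the list alone, with ALDH1A3 at 24.2 ± 0.210 and 26.9 ± 0.688 FPKM (SD, n = 3). In fry, which tests whether the genes of a list move on balance in 1 direction, this list passed (adjusted p = 0.0356), as did the hypoxia list (adjusted p = 0.0151). In camera the stemness list did not pass (adjusted p = 0.3005, and adjusted p = 0.747 with an estimated correlation). Of the 20 interferon-stimulated genes only OASL fell in limma, and BST2 was at 192 ± 4.10 and 190 ± 0.965 FPKM. Of the 19 ferroptosis genes only SLC40A1 rose in limma, and FTL was at 2153 ± 11.8 and 2179 ± 16.5 FPKM. Among the 16 tested MAPK output genes FOSL1 fell from 26.5 ± 0.543 to 20.6 ± 1.27 FPKM over the list alone, and over all genes in limma-voom (adjusted p = 0.0210). Of the 25 tested ATF4 and amino acid response genes, the amino acid transporter gene SLC7A5 fell from 97.3 ± 3.56 to 79.6 ± 0.120 and ATF4 from 105 ± 1.31 to 94.8 ± 1.78 FPKM over the list alone, and SLC7A5 also over all genes in limma-voom (adjusted p = 0.00615). In limma and in limma-voom no member passed in the 14 immediate early genes, the 12 NF-kappaB and inflammatory cytokine genes, the 15 genes of MHC class I presentation, the 18 heat shock genes, the 20 unfolded protein response chaperones, the 25 NRF2 target genes or the 27 autophagy and lysosome genes.

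Among metabolic and housekeeping lists, no member passed in limma or in limma-voom in the 21 glycolysis genes, the 20 fatty acid synthesis genes, the 39 ribosomal proteins of the large subunit or the 13 mitochondrially encoded mRNAs. Of the 40 nuclear oxidative phosphorylation genes none passed in limma, and NDUFB5 and SDHD rose in limma-voom (adjusted p = 0.0340 and 0.0416). GAPDH was at 1052 ± 45.7 and 1012 ± 26.9, ATP5F1B at 792 ± 12.6 and 788 ± 23.3, and SCD at 227 ± 8.97 and 254 ± 3.28 FPKM in shNC and shPAK5 (SD, n = 3). Of the 24 cholesterol synthesis genes CYP51A1 fell from 4.59 ± 0.175 to 3.59 ± 0.207 FPKM over the list alone, a gene with 83.2% of its exonic bases overlapped by other genes. In 10 lists the sign of the median or mean change differed from the direction of the camera test, all with an unadjusted camera p of at least 0.551.

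Levels of cell-state genes are given for the shNC libraries. Keratins of simple epithelia were among the most abundant mRNAs, with KRT19 at 1410 ± 48.1, KRT8 at 1006 ± 31.7 and KRT18 at 874 ± 14.5 FPKM in shNC (SD, n = 3), and the median of the epithelial list, 6.10 FPKM, lay at the 98.2 percentile of 10000 random lists of protein-coding genes of that size. Lists unrelated to cell state, such as immediate early genes, lay as high. The mesenchymal list had a median of 0.519 FPKM, at the 33.2 percentile. VIM, S100A4 at 1704 ± 118 FPKM and the EMT transcription factor gene ZEB1 at 2.58 ± 0.196 FPKM were present, whereas FN1 was at 0.0319 ± 0.0201 and SPARC at 0.174 ± 0.0384 FPKM, and CDH2, TWIST1 and COL6A2 had 0 reads in all 6 libraries. Of the 7 tested genes of luminal and basal breast epithelium none passed, and ESR1 was at 0.00143 ± 0.00248 FPKM and KRT5 at 38.7 ± 1.75. Lists of other cell types were low. The medians were 0.0387 FPKM for fibroblasts and perivascular cells, although LUM was at 111 ± 11.9 FPKM, 0.0132 FPKM for leukocytes and endothelium, and 0 for neurons and embryonic kidney lines, and these 3 lists had too few expressed members to be tested.

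**Figure D3:**
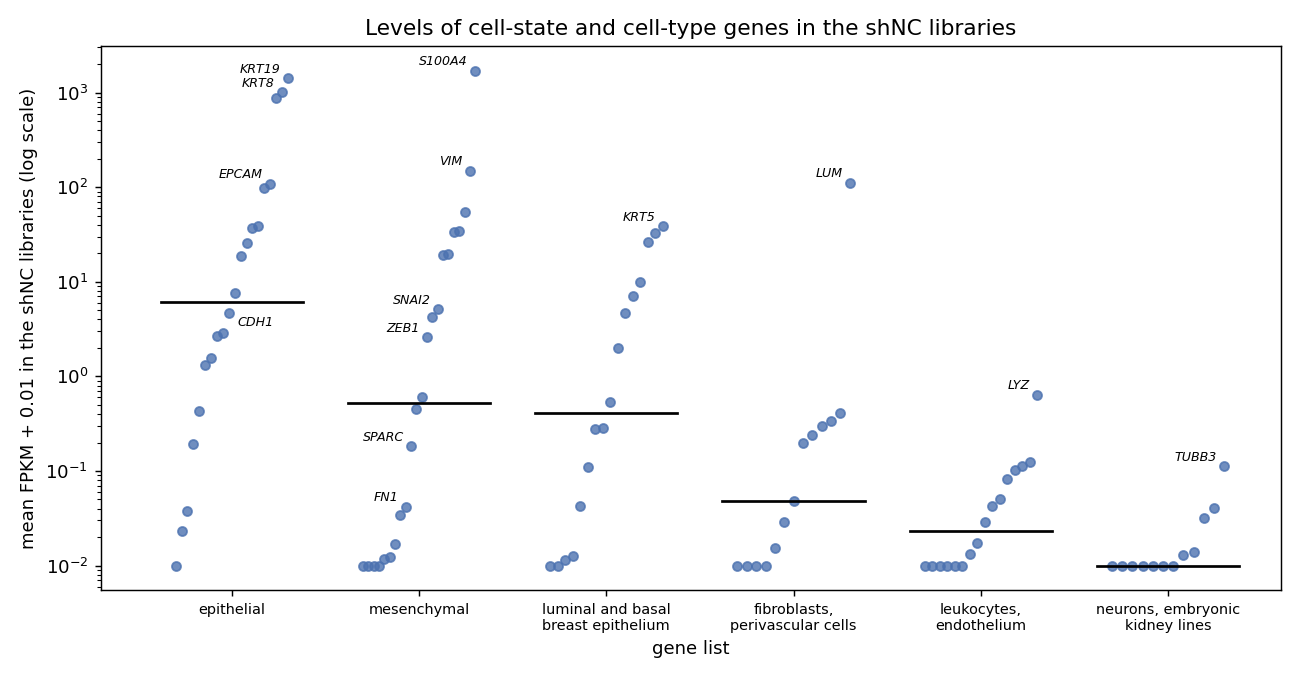
Mean FPKM in the 3 shNC libraries of each member of 6 gene lists fixed before the data were examined, on a log axis after adding 0.01. Points are genes, sorted within each list, and horizontal lines are list medians. The median is 6.10 FPKM for epithelial genes and 0.519 FPKM for mesenchymal genes.

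Before a correction for GC content the libraries did not separate by group alone. The first principal component of the 11237 tested genes held 36.6% of the variance and placed shNC replicate 1 at -3.39, next to shPAK5 replicates 1 to 3 at -8.51, -6.71 and -4.87, and apart from shNC replicates 2 and 3 at 16.2 and 7.31. The differences between libraries followed the GC content of the transcripts. Across 11234 genes with a known GC content, the Spearman rho with GC content was 0.622 for shNC replicate 2 minus shNC replicate 1 and 0.584 for shNC replicate 3 minus shNC replicate 1, and -0.470 for the change of shPAK5 against shNC. Genes are not independent replicates, so no p-value is given for these. The median change was 0.08 on the log2 scale in the third of the genes with the lowest GC content and -0.05 in the third with the highest. After subtraction of each library's trend with GC content, a correction chosen after seeing the data, 52 genes passed (limma), 40 higher and 12 lower, with all 13 genes among them. With the correction and 1 library left out, the count was 27 without shNC replicate 1, 13 without shNC replicate 2, 6 without shNC replicate 3 and 7 without each of the shPAK5 replicates. After the correction the camera adjusted p was 7.27e-09 for the G2/M list and 2.49e-05 for the hypoxia list, and the adjusted p was 0.114 for both with an estimated correlation. The first principal component then held 29% of the variance and placed the shNC libraries at -1.15, -13.1 and -4.93 and the shPAK5 libraries at 7.79, 6.18 and 5.22.

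**Figure D4:**
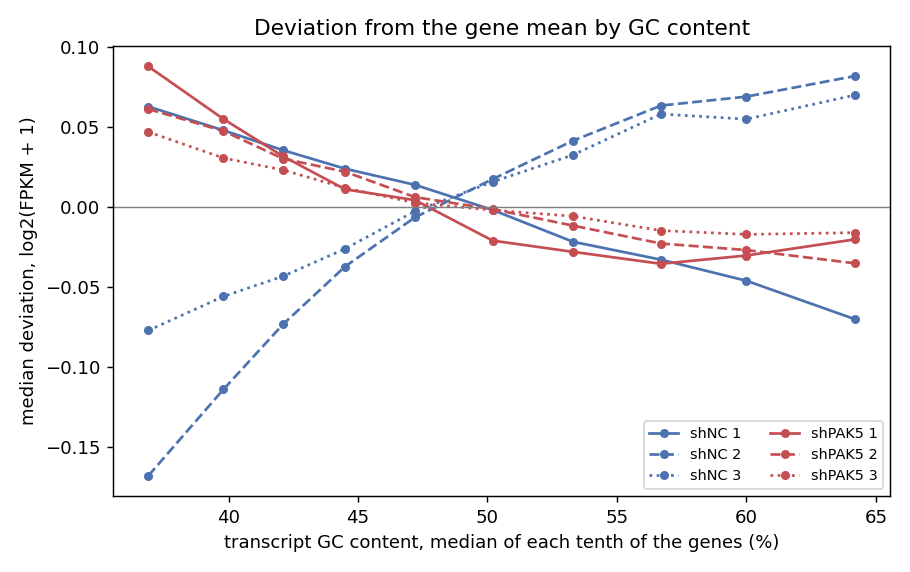
Median deviation from each gene's mean over the 6 libraries, in log2(FPKM + 1), for 10 bins of tested genes ordered by transcript GC content (%). Lines are libraries, blue for shNC and red for shPAK5. shNC replicates 2 and 3 rise with GC content, while shNC replicate 1 falls with it like the 3 shPAK5 libraries.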

Additional observations from a re-analysis of the deposited data

How the results depend on the processing

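The GC correction, alone, with limma-voom and with libraries left out, was chosen after seeing the data, and the other alternatives were planned. The direction of each of the 11 named genes held in every alternative. That was nearly fixed in advance, since the rule required groups without overlap and the alternatives refit the same libraries. ALDH1A1 and SNCG also stayed past adjusted p 0.05 in each of 27 alternatives. The other 9 genes fell short in 5 to 16 of the alternatives that tested them, 100 of 296 gene results in all, 78 of them in fits without a library, with adjusted p-values up to 0.254 for OASL. PAK5 gave no value in any fit, since it had 0 reads, and the planned median-of-ratios scaling moved nothing because the values were already scaled so. The camera test does not use the variance model, so trend=FALSE and robust=TRUE gave no list result. Against 13 genes (10 higher, 3 lower), counts were 7 (5 higher) with no filter, which tests more genes and kept 3 of the 13. At a mean of at least 5 FPKM there were 31 (19 and 12), and 64 (44 and 20) for protein-coding genes only. Quantile normalization gave 20 (7 lower), arrayWeights 3187 (1685 and 1502) and limma-voom 117 (95 and 22). The GC correction gave 52 (40 and 12), and 248 (157 and 91) together with limma-voom. Lower genes numbered 1 with trend=FALSE and 6 with robust=TRUE. The limma treat test against a fold of 1.5 called 0 genes, like the count of 0 at 2-fold. With at least a 2-fold change, 0 genes became 1 at a pseudocount of 0.1, 1 at 0.01, 1 with TPM scaling, 21 with arrayWeights and 2 with the GC correction and limma-voom. Against 2 gene lists, 3 passed at a mean of at least 5 FPKM, where replication-dependent histones were added, 1 with arrayWeights, 5 with the GC correction, 6 with the GC correction and limma-voom and 0 with an estimated correlation. Leaving out 1 library gave 2 to 915 genes, 1 to 606 higher, 1 to 309 lower, 0 to 5 with a 2-fold change and 1 to 4 lists. The value of 915 came without shNC replicate 1, and it was 27 when the GC correction was added. With the GC correction there were 13 without shNC replicate 2, 6 without shNC replicate 3 and 7 without each shPAK5 replicate. Without shNC replicate 2 there were 5 genes, and 2 without each of shNC replicate 3 and shPAK5 replicates 1, 2 and 3. With a replicate block there were 2 genes, 1 higher and 1 lower, and the same 2 lists passed. Residuals of same-numbered libraries correlated at 0.0654, -0.0239 and 0.00898, and those of differently numbered libraries at -0.0847 to 0.0777. No clear pairing by number was seen, although so few libraries cannot exclude one. Some settings leave fewer genes or libraries, and the cause of these differences was not tested. Depth limits what can be said of genes near the floor, such as PAK5 and MT-TQ.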

Other observations

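The GC correction and the tests of PAK5, of lineage genes, of the gastrointestinal list, of the GC trend and of other splits were chosen after the results they bear on were seen, while the tests of the 13 genes, the G2/M list and the hypoxia list under the correction were written before their outcome was seen. Under the GC correction (limma), 52 genes passed, and 35 of them also passed in limma-voom with and without the correction, 26 higher and 9 lower, of which 23 had not passed in limma without the correction. The genes named in this paragraph were chosen after their values were seen. COL17A1, a hemidesmosome collagen, was at 37.6 ± 1.69 FPKM in shNC and 48.8 ± 1.59 in shPAK5 (SD, n = 3; limma adjusted p = 0.0077 with the GC correction), and the fatty acid binding protein gene FABP3 at 9.62 ± 0.916 and 14.0 ± 0.440 (limma adjusted p = 0.0273). Also among the rises were GPA33 at 75.7 ± 3.89 and 89.8 ± 3.43, the aminopeptidase gene ANPEP at 68.8 ± 3.34 and 80.1 ± 2.79 and the mucin glycosyltransferase gene GCNT3 at 9.29 ± 0.217 and 11.7 ± 0.0974 FPKM. The KIT ligand gene KITLG was at 17.0 ± 1.74 and 22.3 ± 0.418 FPKM. On the falling side, CRABP2, a carrier of retinoic acid, was at 12.8 ± 0.805 and 8.61 ± 0.784 FPKM (limma adjusted p = 0.0304), opposite in sign to ALDH1A1, and the amino acid transporter gene SLC7A5 at 97.3 ± 3.56 and 79.6 ± 0.120 FPKM (limma adjusted p = 0.0221).

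With the GC correction the G2/M list had 32 of 35 changes negative and 19 members fell when adjusted over the list alone, and 7 hypoxia genes rose in the same sense, CA9 and BNIP3L also over all genes. The replication-dependent histones (adjusted p = 0.0249), MHC class I presentation (adjusted p = 0.0309) and G1/S genes (adjusted p = 0.0486) passed camera in addition. For the histones the groups overlapped, with a mean deviation of -0.0226 in shPAK5 replicate 3 and 0.0260 in shNC replicate 1. In fry the adjusted p was 0.155 for the histones, 0.0177 for MHC class I presentation and 0.0217 for G1/S genes. The fry adjusted p was 0.0155 for the G2/M list and 0.00666 for the hypoxia list. With an estimated correlation in camera no list passed (adjusted p = 0.114 for both the G2/M and the hypoxia lists).

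Genes of a list of gastrointestinal epithelium, which holds VIL1 and GPA33 and is not independent evidence of its direction, were higher in shPAK5, with 13 of 15 tested members positive and a median change of 0.15 on the log2 scale (camera unadjusted p = 4.89e-06, and p = 0.00816 with an estimated correlation). In limma 1 member passed over all genes and 10 rose when adjusted over the list alone. CDH17 was at 537 ± 2.93 FPKM in shNC and 584 ± 7.33 in shPAK5 (SD, n = 3), LGALS4 at 28.9 ± 0.493 and 33.2 ± 0.412 and MUC13 at 40.4 ± 1.93 and 45.5 ± 0.376. With the GC correction the camera p was 1.49e-07 (p = 0.00495 with an estimated correlation), and leaving out each library in turn gave 1.41e-06 to 0.000306, the highest without shNC replicate 1 (p = 0.0394 with an estimated correlation).

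The change of shPAK5 against shNC followed GC content (Spearman rho -0.470 across genes). A bias of single libraries would make libraries of the same group differ along GC content, and they did, with a rho of up to 0.622 in size between 2 shNC libraries, so the trend itself is consistent with library GC bias. The median change was 0.08 on the log2 scale over the 3745 genes of lowest GC content and -0.05 over the 3745 of highest. The smallest of the 13 changes was -0.37, for OASL. Subtracting so small a trend could hardly remove the 13 calls, so their survival of the correction tests little. These sizes argue against the smooth trend as the whole cause of the 13 calls. A GC bias particular to single genes was not tested. The mean change was nearer to the trend in size for the G2/M list (-0.07) and the hypoxia list (0.14). For these lists the correction argues against the trend as the whole cause, with a camera adjusted p of 7.27e-09 and 2.49e-05. With an estimated correlation, however, neither list passed before the correction or after it (adjusted p = 0.114 for both after it). An effect of the shRNA on these genes stays open, as a hypothesis, beside any difference between cultures that the labels do not record.

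The 6 samples make 10 splits of 3 against 3, too few for a share under 0.05. The real split gave 13 genes and the highest of the others 1, and 1 of the 10 splits gave as many, the real one. For limma-voom the real value was 117 and for the GC correction 52, each against a highest other value of 1, again with 1 split as large. For gene lists the real value was 2 and the highest other 2, and 3 of the 10 splits gave as many. Lists passing with the GC correction were not counted over the splits.

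PAK5 was at 0 reads in all 6 libraries, the controls included. Reads lost to near-identical copies are argued against, since 0% of the 4973 words of 50 bases in its transcripts occurred in other genes, and no other gene overlaps its exons. A level below what the depth can show stays open, because 3 reads over the pooled shNC libraries correspond to 0.0119 FPKM and no value here reaches below that. Whether the shRNA lowered PAK5 cannot be read from these values.

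The lineage genes of these libraries were not those expected of the labelled line, and as a hypothesis the libraries may come from another line than the labelled one; the design gives no biological explanation for these levels to test. MDA-MB-231 is known to have lost CDKN2A, which was at 33.4 FPKM in the shNC libraries (14072 reads over all 6), with only 7.88% of its exonic bases overlapped by another gene. Of the same list, CDH1, known to be silenced in that line, was at 4.64 FPKM, and LDHB was at 0 reads with 33.4% of its exonic bases overlapped, so that its level is uncertain. A list of 27 genes of gastrointestinal epithelium, 1 of which is also in a list fixed before, had a median of 6.27 FPKM, at the 99.4 percentile of random lists, led by CDH17 at 537, TM4SF4 at 276, LGALS2 at 188 and TSPAN8 at 136 FPKM, while CDX1 had 0 reads and MUC2 was at 0.00158 FPKM. That list was written after these levels had been seen, so its percentile was fixed by the choice and does not count as support for another line. Lists unrelated to lineage, such as immediate early genes, lay as high. A minor share of other cells in the labelled line lacks the values it needs, since the mesenchymal list lay at the 33.2 percentile, COL6A2 had 0 reads, and in a share of 10% CDH17 would need 5369 FPKM where the most abundant nuclear mRNA here, TMSB10, was at 3713, but it is not excluded, because the list would need only 4.42% of that share's reads and no measured profile of the labelled line was used here.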
